A study of Trichodesmium erythraeum IMS101 with 4 samples.

How the data were processed

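RNA from Trichodesmium erythraeum IMS101, a filamentous marine cyanobacterium that fixes N2, was sequenced from 4 samples in 2 groups of 2. Per the labels' protocols, cells were collected on filters at midday and frozen, RNA was depleted of rRNA with Ribo-Zero, and libraries were made with a stranded TruSeq mRNA kit and read as single-end reads of 50 bases. The 750-selected group had grown at 750 µatm CO2 for 4.5 years. The 750s-to-380 group came from the same lines after 2 weeks, about 5 generations, at 380 µatm CO2. RNA libraries of lines selected at 380 µatm CO2 were not analysed here.

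The values are whole-number read counts per locus tag, deposited as 1 table of 4615 rows and 4 columns. The submitters' processing notes name Trimmomatic 0.35 and Bowtie2 2.2.6. The counting program, the genome build, the annotation and whether counting used strand are not given in the sources used here. Reads shared by near-identical genes or by overlapping antisense genes can therefore be split or added in ways the table does not show, and no coordinates are given. The columns were matched to the samples by the names they share with the sample titles.

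Library totals were 27547533 and 37054098 counts in 750-selected replicates 1 and 2, and 25125937 and 30889601 counts in 750s-to-380 replicates 1 and 2. At these depths 3 counts, the limit that a count of 0 allows, corresponded to between 0.081 and 0.119 CPM (counts scaled to the same library total). That limit covers counting error only. The 10 most abundant genes took between 18.7% and 20.5% of the counts of a library. No row was listed as rRNA or tRNA, and 1 row was at 0 in all 4 libraries.

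The order of genes was taken from the numbers in their locus tags. Gene names came from a RefSeq table of assembly ASM1426v1, which also gave coding lengths and the listing of pseudogenes, rRNA and tRNA. Of the locus tags in the count table, 3982 (86.3%) had an entry there, 613 had a gene symbol, and 102 were listed as pseudogenes. That table pairs locus tags with symbols and gives no product descriptions here, so gene lists were filled by symbol and genes without a symbol are given by locus tag.

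Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, which left 4476 genes and removed 139, libraries were scaled by TMM, and a quasi-likelihood model with robust priors gave p-values that were adjusted by the Benjamini-Hochberg method. Genes at an adjusted p under 0.05 were called. Fold changes are 750s-to-380 over 750-selected on the log2 scale, with standard errors (SE) from the fitted model, and levels are TMM-scaled CPM. Log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists with 5 or more tested genes.

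The comparison, the 31 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule takes, in each direction, the 8 called genes with the largest folds. With fewer than 10 calls it takes instead the 10 genes with the smallest unadjusted p and a mean count of at least 50 in the higher group. It adds called members of the lists, 16 symbols named whatever their result, and the 5 genes with the highest CPM. Of the 16 symbols 9 were found, psbA in 3 copies, and the rule gave 24 genes. A further 9 lists were written after the gene symbols had been seen and before any fold was computed.

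On simulated counts for the 4476 genes with the spread of these libraries, edgeR recovered 3 of 50 genes changed 1.5-fold, 25 of 50 changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 8-fold, and called 7 of 4276 unchanged genes. In the same simulation 94.84% of the 95% intervals held the true fold. The simulation drew each gene independently, gave both groups the same spread and changed the genes of all these folds at once. In the real libraries neighbouring genes moved together and the spread differed between the groups. With fewer changed genes the adjustment is also stricter, so these recoveries can be higher than those of the real comparison.

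The alternatives were DESeq2 1.42.0, limma voom, RLE and upper-quartile factors, library totals alone, no filter, a filter of at least 50 counts in every library of a group, removal of the 10 most abundant genes, priors that were not robust, a test against a 1.5-fold change, an adjusted p under 0.1, the replicate number as a block, each library left out in turn, and camera with an estimated correlation or fry for the lists. Camera with an estimated correlation and 1 library left out was added after the data were seen. The series text calls the samples of a group biological replicates without saying whether they were separate cultures, so p-values measure only the spread between these samples. Replicate pairs were compared gene by gene before averaging, and chi-square values per degree of freedom of 362 and 154 rule out only that the files of a pair repeat 1 library. That the libraries are replicates rests on the series text.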

Results

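RNA of Trichodesmium was counted in 2 libraries of cells that stayed at 750 µatm CO2 (750-selected) and 2 libraries of cells moved from 750 to 380 µatm CO2 for 2 weeks (750s-to-380). The comparison asks which transcripts differ when cells selected at high CO2 for 4.5 years are returned to the lower concentration. The libraries held between 25125937 and 37054098 counts.

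Single genes set 750-selected replicate 1 apart from the other 3 libraries. Among genes chosen after their values were seen, a phnD gene (Tery_4993), which encodes the binding protein of a phosphonate transporter, stood at 64.2 CPM in 750-selected replicate 1, against 14.7 CPM in 750-selected replicate 2 and 14.2 and 13.8 CPM in 750s-to-380 replicates 1 and 2. The other phnD gene (Tery_0366) stood at 126 and 101 CPM in 750-selected and at 113 and 108 CPM in 750s-to-380. One of the ctaD genes (Tery_1778), for a cytochrome oxidase subunit, stood at 698 CPM in 750-selected replicate 1 and at 171, 169 and 164 CPM in the other libraries, while another (Tery_0277) was lowest in that library, at 234 CPM against 536, 707 and 404 CPM. The petJ gene (Tery_2561), for the electron carrier cytochrome c6, was also lowest there, with 333 CPM in 750-selected replicate 1 against 1370, 1310 and 825 CPM. In 4118 genes with a mean count of at least 50, 750-selected replicate 1 was over 2-fold above the next library for 61 genes and over 2-fold below it for 25 genes. The same counts were 3 and 7 in 750-selected replicate 2, 10 and 2 in 750s-to-380 replicate 1, and 3 and 0 in 750s-to-380 replicate 2.

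Over the 4476 genes tested, the SD of the log2 difference was 0.556 between the 750-selected libraries and 0.32 between the 750s-to-380 libraries. In the first pair 334 genes (7.46%) differed over 2-fold, and in the second 83 genes (1.85%). Pearson correlations across genes, which are not independent replicates, were 0.9801 and 0.9934, and Spearman correlations were 0.9777 and 0.9944. Between groups, 750-selected replicate 2 and 750s-to-380 replicate 2 had an SD of 0.343 and a Pearson correlation of 0.9925. The first principal component held 56.1% of the variance and placed 750-selected replicate 1 at -22.06 and replicate 2 at 14.15, with the 750s-to-380 libraries at 5.75 and 2.17 between them.

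**Figure D1:**
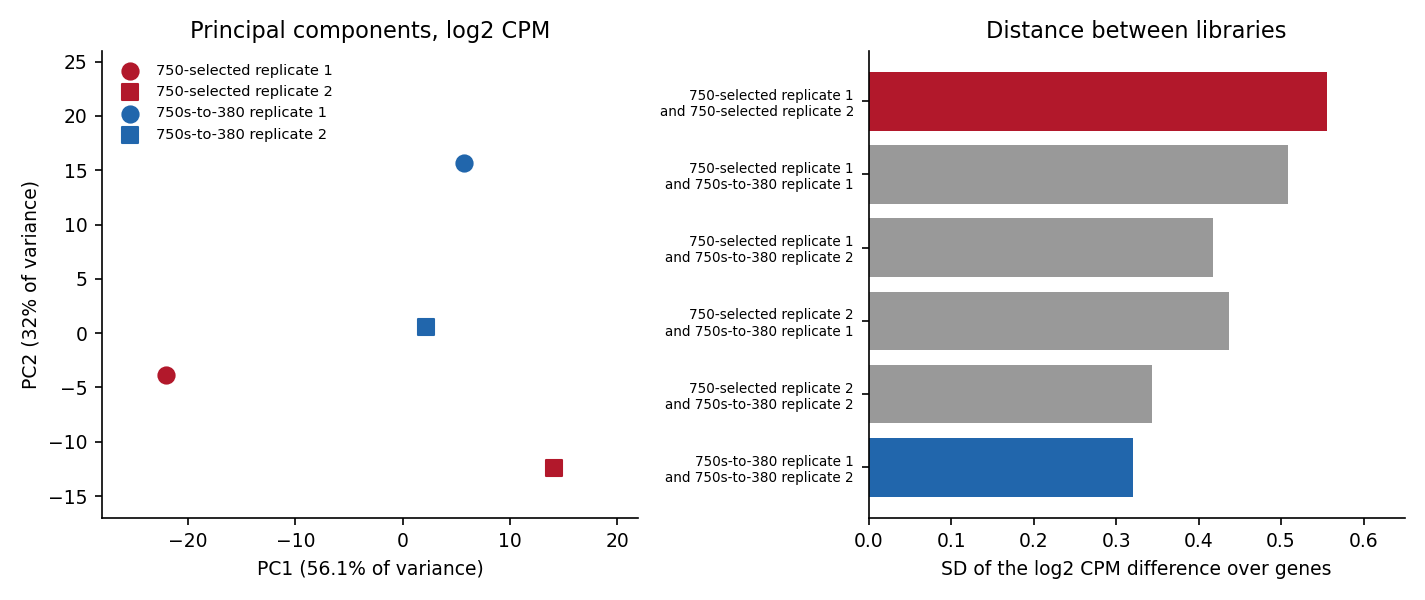
Left, principal components 1 and 2 of log2 CPM for the 4 libraries, with percent of variance on each axis; right, SD over 4476 genes of the log2 CPM difference for each pair of libraries, red and blue for pairs of 1 group and grey for pairs across groups. The 750-selected pair has the largest SD (0.556) and the 750s-to-380 pair the smallest (0.32).

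The 10 genes with the smallest p were all higher in 750s-to-380 without passing the threshold, and 8 of them lie in 2 stretches of the genome. Of these, Tery_0840, Tery_0841, Tery_0843, Tery_0844 and Tery_0845 lie in 1 stretch of locus tags and Tery_2483, Tery_2484 and Tery_2485 in another, while Tery_0467 and Tery_4281 neighbour none of the others, and none of the 10 has a symbol in the name table. Tery_0843 stood at 63.3 ± 0.3 CPM (mean ± SD, n = 2) in 750-selected and at 112.7 ± 0.135 CPM (n = 2) in 750s-to-380, a log2 fold of 0.83 (SE 0.136). Tery_0845, the most abundant of them, stood at 710.2 ± 103 CPM (n = 2) and 1179 ± 71.8 CPM (n = 2), a log2 fold of 0.73 (SE 0.17). The log2 folds of Tery_2483, Tery_2484 and Tery_2485 were 0.96, 0.96 and 0.92 (SE 0.159, 0.168 and 0.166).

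Of the other genes in this set, Tery_0467 had a log2 fold of 1.15 (SE 0.252), Tery_0840 1.14 (SE 0.251), Tery_0841 0.84 (SE 0.16), Tery_4281 0.81 (SE 0.169) and Tery_0844 0.69 (SE 0.131). With edgeR and Benjamini-Hochberg adjustment all 10 had an adjusted p of 0.992. All were higher in both 750s-to-380 libraries than in either 750-selected library. Choosing genes by the smallest p in the same libraries favours this, so it adds no support. Among named genes, hemW (Tery_1194), a relative of coproporphyrinogen oxidases that binds heme, was chosen after its values were seen and stood at 1105 ± 216.8 CPM (n = 2) in 750-selected and 1933 ± 254.9 CPM (n = 2) in 750s-to-380, a log2 fold of 0.81 (SE 0.208) that did not pass the threshold.

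The 5 most abundant transcripts encoded photosystem and gas vesicle proteins, and none passed the threshold. The psbA gene Tery_4763, for the D1 protein of photosystem II, stood at 29280 ± 9177 CPM (n = 2) in 750-selected and 26950 ± 1267 CPM (n = 2) in 750s-to-380, a log2 fold of -0.12 (SE 0.258). The psaA (Tery_4669) and psaB (Tery_4668) genes, for the reaction centre of photosystem I, had log2 folds of -0.26 (SE 0.181) and -0.20 (SE 0.179). Without 750-selected replicate 1 these were -0.08 and -0.02. The gvpA genes Tery_2325 and Tery_2324, for the main gas vesicle protein, had log2 folds of 0.17 (SE 0.302) and 0.14 (SE 0.34). The other psbA copies, Tery_0182 and Tery_0183, had log2 folds of 0.01 (SE 0.246) and -0.01 (SE 0.247), and that of the second was above 0 with library totals as the scaling (0.02), by limma voom (0.03), and without 750-selected replicate 2 (0.34) or 750s-to-380 replicate 1 (0.02). Leaving out 1 library of 750-selected also turned the sign of the others, to 0.25 for Tery_4763 without replicate 2 and -0.27 for Tery_0182 without replicate 1, and without replicate 2 the gvpA folds were -0.13 and -0.20 (-0.05 and -0.12 without 750s-to-380 replicate 1). Counts of the 3 psbA copies, and of the paired gvpA genes, are uncertain because such copies can share reads.

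Of the regulators and housekeeping genes named in advance, rpoD (Tery_5068), for the principal sigma factor, stood at 1507 ± 19.4 CPM (n = 2) in 750-selected and 1541 ± 4.59 CPM (n = 2) in 750s-to-380. The nitrogen regulator gene ntcA (Tery_2023) had a log2 fold of 0.12 (SE 0.138), petH (Tery_3658), for ferredoxin-NADP reductase, -0.12 (SE 0.175), and glnA (Tery_3834), for glutamine synthetase, 0.24 (SE 0.336). Without 750-selected replicate 1 glnA had -0.14, and without replicate 2 petH had 0.03.

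**Figure D2:**
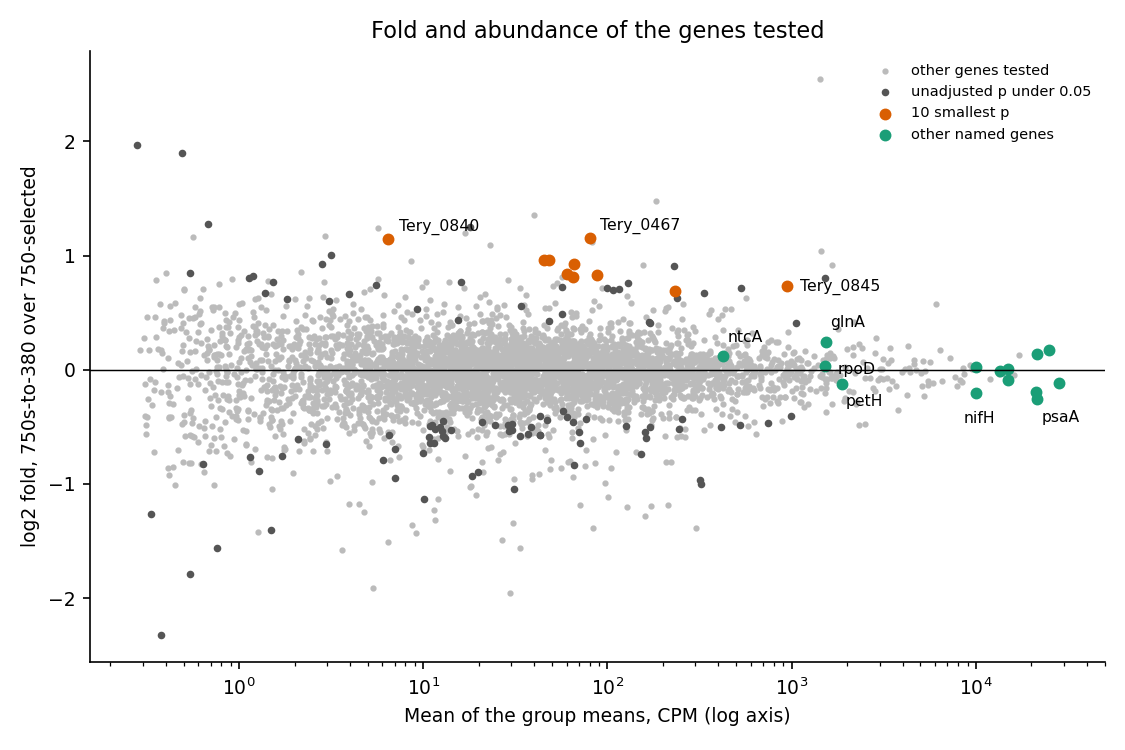
The log2 fold of 750s-to-380 over 750-selected against mean abundance in CPM (log axis) for the 4476 genes tested, with the 10 genes of smallest p in orange, the other named genes in green and genes at unadjusted p under 0.05 in dark grey. The 10 genes of smallest p lie between log2 folds of 0.69 and 1.15, and the most abundant named genes lie near 0.

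By edgeR 0 of 4476 genes passed an adjusted p of 0.05 in either direction. At an unadjusted p under 0.05 stood 109 genes, 44 higher and 65 lower in 750s-to-380, where 5% of the genes tested is 224. With library totals as the scaling they were 48 higher and 30 lower. DESeq2, run on 4614 genes without the filter, and limma voom also called 0 genes, with 124 and 102 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.992 by edgeR, 0.155 by DESeq2 and 0.995 by limma voom. The groups did not overlap for 1333 genes (29.8%), and chance gives 33.3% for 2 against 2. The 95% interval of the fold lay within 2-fold in either direction for 3320 genes (74.2%) and within 4-fold for 4355 genes (97.3%), which leaves smaller changes open. Leaving out 750-selected replicate 2 gave 279 calls by edgeR, 94 higher and 185 lower, in a fit that assumes the lone 750-selected library to vary like the other group, while leaving out any other library gave 0.

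Genes of N2 fixation had log2 folds between -0.21 and 0.29 and differed together between the replicates of each group. The nifH gene (Tery_4136), for the iron protein of nitrogenase, stood at 10770 ± 3415 CPM (n = 2) in 750-selected and 9331 ± 4193 CPM (n = 2) in 750s-to-380, a log2 fold of -0.21 (SE 0.401). The genes nifD (Tery_4137) and nifK (Tery_4138), for the molybdenum-iron protein, had log2 folds of -0.09 (SE 0.378) and 0.02 (SE 0.381), and nifK had -0.05 by limma voom. The folds of nifH and nifD were above 0 without 750-selected replicate 2 (0.17 and 0.14) or 750s-to-380 replicate 2 (0.19 and 0.32), and that of nifK was below 0 without replicate 1 of either group (-0.16 and -0.56). All 9 genes of the list were higher in 750-selected replicate 2 than in replicate 1, and all 9 were higher in 750s-to-380 replicate 1 than in replicate 2. For nifH the values were 8358 and 13190 CPM in 750-selected and 12300 and 6367 CPM in 750s-to-380.

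None of the 9 nitrogenase genes passed the edgeR test over all genes or adjusted over the list alone, and 0 stood at an unadjusted p under 0.05. DESeq2 and limma voom called 0 of them. The fixed list for the CO2 concentrating mechanism and Rubisco had 0 members, because none of its genes has a symbol in the name table, and those genes were not analysed here by name. Leaving out 750s-to-380 replicate 1 gave the nitrogenase list a median log2 fold of -0.56, and leaving out replicate 2 gave 0.55. In both fits the list passed camera with the preset correlation (Benjamini-Hochberg adjusted p = 8.85e-08 and 2.28e-04), and in neither with an estimated correlation (adjusted p = 0.981 and 0.87). With all 4 libraries the estimated correlation between its genes was 0.96, and camera gave p = 0.952 with it.

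**Figure D3:**
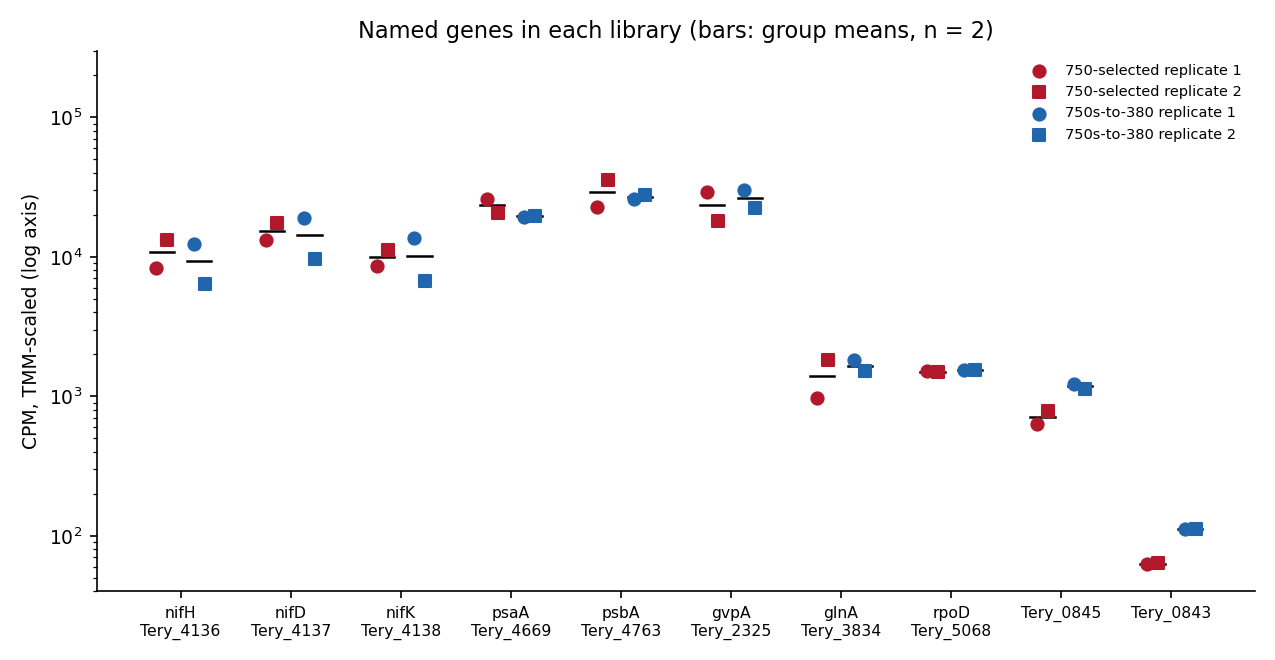
Level of 10 named genes in each of the 4 libraries in TMM-scaled CPM (log axis), with circles for replicate 1, squares for replicate 2 and bars for the group means (n = 2). The nifH points span 8358 to 13190 CPM in 750-selected and 6367 to 12300 CPM in 750s-to-380, while both Tery_0843 points of 750s-to-380 lie above those of 750-selected.

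Central carbon metabolism, lower in 750s-to-380, and photosystem II, higher, had the smallest p of the lists by camera with its preset correlation, and neither passed the test. Of 26 genes of central carbon metabolism 19 had log2 folds below 0 and 7 above, with a median of -0.07 and a mean of -0.20. The glycogen debranching genes glgX had log2 folds of -0.89 (Tery_1895), -0.59 (Tery_5016) and 0.02 (Tery_3430), the pyruvate kinase gene pyk (Tery_2926) -0.86 (SE 0.354) and the transketolase gene tkt (Tery_0450) -0.07 (SE 0.141). The lowest fold of the list was that of gap (Tery_2881), at -1.10, and the highest were those of the neighbours opcA (Tery_0685) and zwf (Tery_0684), at 0.55 and 0.44. Without 750-selected replicate 1 the 3 glgX genes had -0.16, -0.37 and -0.08 and pyk had -0.27. In that fit gap, opcA and zwf had 0.05, 0.04 and 0.07. Of 21 photosystem II genes 15 had log2 folds above 0 and 6 below, with a median of 0.05 and a mean of 0.13. The genes psb34 (Tery_2220), at 0.92 (SE 0.41), and psb28 (Tery_2408), at 0.63 (SE 0.448), had the largest folds of the list, and psbD (Tery_1230) had 0.10 (SE 0.166). Leaving out 1 library moved psb34 to between 0.46 and 1.42, psb28 to between 0.16 and 1.33 and psbD to between -0.02 and 0.24. By camera with Benjamini-Hochberg adjustment over 18 lists, the adjusted p was 0.193 for central carbon metabolism and 0.236 for photosystem II, the latter shared with photosystem I, phosphorus, hydrogenases and cell division. With an estimated correlation camera gave an unadjusted p = 0.104 for central carbon metabolism, 0.181 for cell division, 0.212 for photosystem I and 0.557 for photosystem II, and by fry the smallest was p = 0.0419 for cell division. Photosystem II genes were lowest in 750-selected replicate 1, at a mean log2 deviation of -0.32. Their median was -0.16 without that library (camera adjusted p = 0.0846) and 0.34 without replicate 2 (camera adjusted p = 2.93e-06, and 0.798 with an estimated correlation). The median of central carbon metabolism was 1.36e-04 without 750-selected replicate 2 (camera adjusted p = 0.478), -0.15 without replicate 1 (0.0075, and 0.889 with an estimated correlation), -0.09 without 750s-to-380 replicate 1 (0.0473, and 0.981) and -0.10 without 750s-to-380 replicate 2 (0.301).

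The phosphorus and hydrogenase lists had log2 folds mostly below 0, and both were highest in 750-selected replicate 1. Of 14 phosphorus genes 11 had log2 folds below 0, with a median of -0.13, and the mean deviation of the list was 0.605 in 750-selected replicate 1 against -0.185, -0.196 and -0.223 in the other libraries. The transporter genes phnD (Tery_4993), phnC (Tery_4994) and both neighbouring phnE genes (Tery_4995 and Tery_4996) had log2 folds of -1.49, -1.51, -1.58 and -1.43, and -0.07, -0.04, -0.11 and -0.13 without 750-selected replicate 1. The phnL gene (Tery_5002), the 1 gene of the list at an unadjusted p under 0.05, had -1.41 (SE 0.527) without passing the threshold, and -0.64 without that library. The other phnC (Tery_0365), phnD (Tery_0366) and phnE (Tery_0367) genes had -0.15, -0.05 and -0.06 with all libraries. The pstS genes, for phosphate binding, had -0.04 (Tery_3537) and -0.12 (Tery_3534). The neighbours pstC (Tery_3538), pstA (Tery_3539) and pstB (Tery_3540) had 0.22, 0.16 and 0.10, the 3 folds of the list above 0. Without 750-selected replicate 2 pstB had -0.03. Without 750-selected replicate 1 the median of the phosphorus list was -0.02 (camera adjusted p = 0.858). Of 5 hydrogenase maturation genes 4 had log2 folds below 0, with a median of -0.25, and the mean deviation was 0.497 in 750-selected replicate 1 against -0.191, -0.141 and -0.165, and without that library the median was 0.06. By camera with Benjamini-Hochberg adjustment the adjusted p was 0.236 for each of these lists.

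**Figure D4:**
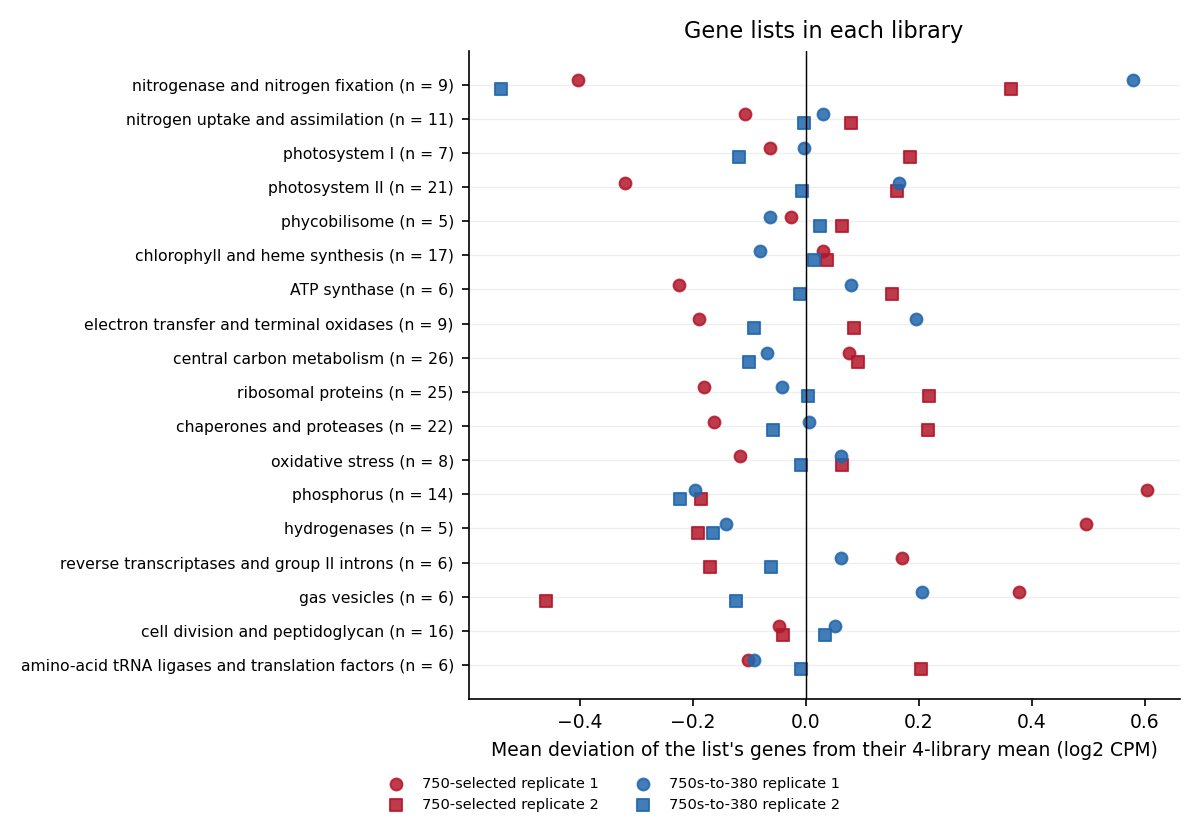
Mean deviation of the genes of each of 18 lists from their mean over the 4 libraries (log2 CPM), with 1 point per library and the number of genes beside each name. In the nitrogenase, phosphorus, hydrogenase and gas vesicle lists the libraries of 1 group lie far apart, as for phosphorus at 0.605 and -0.185 in 750-selected.

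The photosystem I, phycobilisome and pigment lists had medians slightly below 0 in 750s-to-380. Of 7 photosystem I genes 6 had log2 folds below 0 (median -0.15), of 5 phycobilisome genes 4 (median -0.06), and of 17 chlorophyll and heme genes 12 (median -0.11). With 1 library left out these medians ranged from -0.22 to -0.12, from -0.13 to 0.01 and from -0.16 to -0.008. The phycobilisome list held the apcB genes Tery_3649 (-0.13) and Tery_3835 (-0.06), cpcA (Tery_5048, -0.14), nblB (Tery_2239, -0.01) and nblR (Tery_3164, 0.14). The 25 ribosomal protein genes had a median of -0.11 with 16 below 0, the 22 chaperone and protease genes a median of -0.04 with 15 below 0, and the 6 translation factor genes a median of -0.09 with 5 below 0. The 16 genes of cell division and peptidoglycan had a median of 0.04 with 10 above 0, and the 9 genes of electron transfer and terminal oxidases a median of 0.06 with 6 above 0. The 6 ATP synthase genes had a median of 0.05 with 4 above 0, and the 8 oxidative stress genes a median of 0.02 with 4 above 0. With 1 library left out the median ranged from -0.15 to 0.28 for ATP synthase and from -0.03 to 0.17 for oxidative stress. It ranged from -0.05 to 0.20 for electron transfer, from -0.19 to 0.04 for translation factors and from 0.05 to 0.11 for cell division.

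The 6 gas vesicle genes had a median log2 fold of 0.00 with 3 above 0, the 11 genes of nitrogen uptake and assimilation a median of -0.03 with 5 above 0, the 6 reverse transcriptase genes a median of -0.01 with 3 above 0, and the 9 nitrogenase genes a median of 0.10 with 7 above 0. In the nitrogen uptake and reverse transcriptase lists the median and the mean were below 0 while camera gave the upward direction. The nitrogen uptake median was above 0 with library totals as the scaling (0.01), by limma voom (0.06) and without 750-selected replicate 1 (0.01). The reverse transcriptase median was above 0 by limma voom (0.01), without 750-selected replicate 1 (0.28) and without 750s-to-380 replicate 2 (0.09).

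Lists with fewer than 5 tested genes were counted and not tested. The 4 iron genes had a median log2 fold of -0.24, and sufC (Tery_4356) and sufD (Tery_4357), of the iron-sulfur cluster assembly system, had -0.48 (SE 0.17) and -0.44 (SE 0.164) without passing the threshold. The 3 clock genes had a median of -0.43, with kaiB (Tery_3804) at -0.72 (SE 0.489), and kaiB stood at 49.4 CPM in 750-selected replicate 1 against 18.2 CPM in replicate 2 and 19.6 and 21.4 CPM in 750s-to-380. Without 750-selected replicate 1 kaiB had a log2 fold of 0.17, kaiC (Tery_3805) 0.10 and the list a median of 0.10. The 2 sigma factor genes had a median of 0.04, and the lists for NDH-1, mobile elements and signalling had 1 gene each, at 0.07, 0.39 and 0.12. Leaving out 1 library changed the sign of the median in 5 of these 6 lists. Without 750-selected replicate 1 the NDH-1, mobile element and signalling genes had -0.04, -0.02 and -0.29. The sigma factor median was -0.28 without 750-selected replicate 2 and 0.65 without replicate 1. The median of the iron genes stayed below 0, between -0.35 and -0.08. A further 7 lists had no member with a symbol, namely those for the CO2 concentrating mechanism, DNA methyltransferases, CRISPR, toxin-antitoxin systems, adhesion proteins, extracellular polysaccharide, and rRNA and tRNA.

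Of the 18 tested lists 0 passed camera, 2 stood at an unadjusted p under 0.05, and 0 passed with an estimated correlation or with fry. Camera with an estimated correlation has 2 residual degrees of freedom here, and its smallest adjusted p was 0.952. It can therefore detect little, also with all 4 libraries. No list had a member called over all genes or adjusted over the list alone. Leaving out 1 library changed the sign of the median in 14 of the 18 lists, and not in photosystem I, chlorophyll and heme synthesis, phosphorus and cell division. It brought lists past the preset-correlation test in each case: 4 without 750-selected replicate 1 (central carbon metabolism, ribosomal proteins, chaperones and gas vesicles), 7 without 750-selected replicate 2 (photosystem II, ATP synthase, ribosomal proteins, chaperones, phosphorus, hydrogenases and gas vesicles), 3 without 750s-to-380 replicate 1 (nitrogenase, central carbon metabolism and phosphorus) and 1 without 750s-to-380 replicate 2 (nitrogenase). With an estimated correlation 0 passed in each of these fits, an alternative chosen after the data were seen that has 1 residual degree of freedom and so can detect little.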

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

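The count of called genes was 0 in each direction in every alternative run with all 4 libraries: DESeq2, limma voom, the 3 other scalings, both filters, removal of the 10 most abundant genes, priors that were not robust, a test against a 1.5-fold change and an adjusted p under 0.1. With 1 library left out the count by edgeR ranged from 0 to 94 higher and from 0 to 185 lower, and the calls came from the fit without 750-selected replicate 2, where 9 of the 10 genes with the smallest p passed. The common biological coefficient of variation was 20.7% with all libraries, 13.3% without either 750-selected library, and 25.9% and 25.8% without 750s-to-380 replicate 1 or 2. The fit without 750-selected replicate 1 had the same spread as the fit with calls, and 768 and 858 genes stood at an unadjusted p under 0.05 in these fits, against 109 with all libraries. Both fits take their spread from the 750s-to-380 pair alone, so their equal spread follows from the design. They differ only in the 750-selected library kept, and the difference in calls comes from that choice. The fit with calls kept replicate 1, with SDs of the log2 difference to 750s-to-380 replicates 1 and 2 of 0.508 and 0.417. For 750-selected replicate 2 these SDs were 0.437 and 0.343. The fits with 1 library left out assume that the lone library varies like the other group.

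Lists past camera numbered 0 under each scaling and filter, with an estimated correlation and with fry, and ranged from 1 to 7 with 1 library left out. With 1 library left out and an estimated correlation, a combination chosen after the data were seen, they numbered 0. With the preset correlation and 1 library left out, 4 lists passed the test in opposite directions: the median log2 fold ranged from -0.56 to 0.55 for nitrogenase, from -0.26 to 0.069 for ribosomal proteins, from -0.19 to 0.12 for chaperones and proteases, and from -0.29 to 0.58 for gas vesicles. The genes of these lists moved together between the replicates of a group. For nitrogenase the mean deviations in 750s-to-380 replicates 1 and 2 were 0.58 and -0.54. In 750-selected they were -0.181 and 0.219 for ribosomal proteins, -0.163 and 0.216 for chaperones, and 0.378 and -0.46 for gas vesicles. With all 4 libraries the estimated correlations were 0.96, 0.46, 0.54 and 0.98 in that order, against the preset 0.01. Why the genes of these lists differed between replicates was not tested. The nitrogenase genes called stayed at 0 in every fit. With all 4 libraries the sign of a named gene's fold differed from the reported one in 5 of 280 values and that of a list's median in 5 of 161.

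The replicate block gave 0 called genes, 0 lists past the test and 0 nitrogenase genes called, and deviations of same-numbered libraries correlated at -0.03 across genes. The labels do not say whether equal numbers share a line, so no pairing was assumed. With the block the signs differed for psbA Tery_0183 (0.02), nifK (-0.05), and the medians of nitrogen uptake (0.06) and reverse transcriptases (0.0092). With library totals as the scaling the genes at an unadjusted p under 0.05 were 48 higher and 30 lower, against 44 and 65, while the median log2 fold of all genes was 0.01 against -0.02. Pearson correlations of the replicate pairs moved by less than the difference between the pairs under each scaling and filter. List members matched by product description alone were not run, since no product descriptions were at hand. Depth limits the genes with few counts, and 2163 of the 4476 genes tested had a mean count of at least 1000.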

Other observations

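The gene lists in this paragraph were written after the gene symbols had been seen, and the tests of counting depth, of noise in single genes, of the size of scaling shifts and of p-values in other splits, given further on, were chosen after the results were seen. None of the 9 added lists passed camera, 0 stood at an unadjusted camera p under 0.05, and 0 passed with an estimated correlation or fry, whose smallest unadjusted p were 0.0186 for purine and pyrimidine synthesis and 0.0414 for B-vitamins and cofactors. Leaving out 1 library brought 0 of them past camera and changed the sign of the median in 6 of the 9, though not for purine and pyrimidine synthesis, carotenoid synthesis and DNA repair. Of 21 genes of purine and pyrimidine synthesis 15 had log2 folds below 0. Their median was -0.15, and it lay between -0.12 and -0.05 with 1 library left out. Among them carB (Tery_2877), for carbamoyl phosphate synthase, was chosen after its values were seen. It had -0.43 (SE 0.136) and was lower in both 750s-to-380 libraries, which such a choice favours, without passing the threshold. The genes purH (Tery_1128) and guaA (Tery_0907) had larger folds, at -0.95 and -0.80, and 0.38 and -0.19 without 750-selected replicate 1. The list named for hormogonium polysaccharide (hps) genes, known from the motility of other filamentous cyanobacteria, had 12 genes. Of these, 7 had log2 folds above 0 and 5 below (median 0.04, mean -0.04, camera direction down). The 7 include pilM (Tery_1605), ebsA (Tery_2748) and hmpF (Tery_3250), which carry no hps symbol, at 0.12, 0.42 and 0.05. The neighbours hpsA (Tery_4120), hpsB (Tery_4119) and hpsC (Tery_4118), also chosen after their values were seen, had -0.49 (SE 0.157), -0.33 (SE 0.192) and -0.59 (SE 0.266). Leaving out 1 library moved these folds to between -0.61 and -0.36, -0.50 and -0.17, and -0.95 and -0.29. The 51 genes of amino acid synthesis had a median of -0.05 with 31 below 0, the 27 of DNA repair -0.09 with 18 below 0, the 19 of carotenoid and isoprenoid synthesis -0.08 with 15 below 0, the 19 of cobalamin synthesis -0.09 with 12 below 0, the 19 of protein secretion -0.05 with 13 below 0, and the 17 of fatty acid and lipid A synthesis 0.03 with 7 below 0.

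The 38 genes of B-vitamin and cofactor synthesis had a median of -0.01 with 20 below 0, a mean of 0.03 and a downward camera direction. One of them, nadC (Tery_4352), for a step of NAD synthesis, had the widest fold among the genes with a symbol in the lists, at 2.55 (SE 1.24), and was chosen after its values were seen. It stood at 666 and 162 CPM in 750-selected and at 4470 and 378 CPM in 750s-to-380, so the libraries of 1 group differed 11.8-fold, and without 750s-to-380 replicate 1 its log2 fold was -0.12. The methionine synthase genes, also chosen after their values were seen, showed metE (Tery_0847), the cobalamin-independent form, at 4893 ± 1236 CPM (n = 2) in 750-selected and 7277 ± 630.8 CPM (n = 2) in 750s-to-380, a log2 fold of 0.57 (SE 0.227, between 0.34 and 0.86 with 1 library left out) that did not pass the threshold. The metH genes, for the cobalamin-dependent form, had -0.05 (SE 0.151, Tery_1073) and -0.05 (SE 0.523, Tery_2492), and with 1 library left out lay between -0.16 and 0.07 and between -0.64 and 0.94.

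The 750-selected libraries lay further apart than the 750s-to-380 libraries. The tables argue against counting depth as the cause: in 2163 genes with a mean count of at least 1000 the SD expected from counting was 0.039 in the 750-selected pair and 0.041 in the other, a ratio of 0.947, while the observed SDs were 0.519 and 0.269. They also argue against a trend with coding length: after it was removed over 3909 genes with a length (87.3%), the SD was 0.551 (bootstrap interval 0.535 to 0.569) against 0.308 in the 750s-to-380 pair. Before removal the SD was 0.553. The interval resampled genes one by one, and because neighbouring genes moved together it can be too narrow. Extra noise that strikes genes one by one would add no covariance between neighbours and, from that of the 750s-to-380 pair, allow a correlation of 0.0977 (block bootstrap interval 0.065 to 0.138), while the log2 differences of 4038 neighbouring pairs correlated at 0.459 (0.413 to 0.497) in 750-selected and at 0.299 in 750s-to-380. Effects on whole transcripts or on the RNA of a sample, such as the state of a culture or its handling, stay open, and no biological explanation was tested because the labels give both libraries the same condition.

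The stretch of Tery_0838 to Tery_0850, which holds metE, was singled out after its values were seen, and its 12 tested genes were higher in both 750s-to-380 libraries than in either 750-selected library. The values argue against the choice among 4 scalings as the cause, since they moved a library of one group against the other by at most 0.0642 (log2), less than the smallest gap of 0.127 in these genes, and 12 of 12 stayed so under each; a shift that all 4 scalings share stays open. The run of neighbouring genes on 1 side without overlap was 14 genes long, from Tery_0837 to Tery_0851. The longest run in another split of the 4 libraries was 21 genes. Counting the real split itself, 2 of the 3 splits gave a run of at least 14 genes, and 3 splits are too few for a share under 0.05. The move to 380 µatm CO2 stays open as an explanation, as a hypothesis for these genes, but neighbouring genes also moved together between the 750s-to-380 libraries, where their log2 differences correlated at 0.299.

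By edgeR 109 genes stood at an unadjusted p under 0.05 in the real split and 235 in the highest of the others. All 3 splits of the 4 libraries gave at least 109, and 3 splits are too few for a share under 0.05. The other splits set 750-selected replicate 1 beside a 750s-to-380 library. They part the libraries that lay furthest apart, those of 750-selected (SD 0.556), which the real split keeps together. For these counts and for the run of neighbouring genes they are therefore no reference for chance.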
